A study of Mus musculus with 6 samples.

How the data were processed

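Messenger RNA was sequenced from ureteric epithelium of mouse kidneys (CFW strain) at embryonic day 16.5. Per the labels, cells were marked by a pair of fluorescent reporters, a green one driven by Hoxb7, which marks the whole ureteric epithelium, and a red one driven by Wnt11, which marks its growing tips. Cells positive for both reporters made up the tip group, and cells positive for the green reporter alone made up the stalk group, with 3 libraries each. RNA was isolated with a Qiagen RNeasy micro kit and made into stranded poly(A) libraries with a Kapa kit, per the labels' protocols. Nothing states that the libraries came from separate animals or litters, so p-values measured only the spread between these samples, which may be technical.

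The values were RPKM (reads scaled to transcript length and to the mapped reads of the library) computed by the authors, in 1 deposited table. The submitters' processing notes name bcl2fastq 2.17, TopHat2, Partek and the mouse genome build mm10. The gene annotation, the quantification settings and the use of strand were not given in the sources used here. The deposited table held 93615 rows and 6 value columns, each carrying 1 sample's title. In 24545 rows a question mark stood in all 6 columns, and these rows were left out. The other 69070 rows belonged to 21456 gene symbols, of which 11590 had more than 1 row, with up to 41 rows for 1 symbol. Rows of 1 symbol carried no transcript identifier and were treated as isoforms. RPKM values were summed over the rows of each symbol. Low values did not lie on steps of whole reads, so sequencing depth was unknown and no counting interval or detection floor was given. The sum of RPKM per library ranged from 345123 to 366035, which reflects the unit and not the depth. Symbols turned into calendar dates by a spreadsheet numbered 22 and were tested but not named. Of the symbols with values, 19327 were found in the GENCODE M21 annotation of the same genome build, from which coordinates were taken. Since the rows may share reads between near-identical genes, values of close paralogs were treated as uncertain.

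Genes with a mean of at least 1 RPKM over the 6 libraries were tested, 12532 in all. The test was limma 3.58.1 in R 4.3.3, on log2(RPKM + 1), with a linear model of group, moderated variances with a mean-variance trend and no block. Tests were two-sided, with the Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are tip minus stalk on this log2 scale with pseudocount 1, which understates the change of low genes. Ratios of mean RPKM are given where every library of the lower group had at least 0.05 RPKM. The model was tested on simulated data with 200 of 12532 genes changed. It called 69% of genes changed by 1 log2 unit and 93% of those changed by 2 log2 units, and 3.57% of the calls were false. Far fewer genes were changed there than were called in the data, and noise was drawn independently for each gene. These rates therefore need not hold for the real comparison. Quantities of whole libraries were compared with exact two-sided permutation tests, for which 3 against 3 libraries allow no p below 0.1.

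Before the data were examined, 25 gene lists were fixed from general knowledge of kidney development. They cover the sorting reporters, ureteric tip, ureteric stalk, feedback genes of receptor tyrosine kinase and ERK signalling, Wnt targets, Notch, BMP and TGF-beta, DNA replication, mitosis, principal cells, intercalated cells, urothelium, epithelial junctions and keratins, basement membrane and integrins, and glycolysis. Further lists hold markers of cells outside the ureteric epithelium (nephron progenitors, early nephron, podocyte, proximal tubule, loop and distal tubule, stroma, endothelium, immune and erythroid cells) and immediate early and heat shock genes, which respond to tissue dissociation. Members were counted as called after adjustment over all genes and, separately, adjusted over the list alone. The latter count is given where it differed. Each list with at least 5 tested members, 17 in all, was compared with the other genes by camera (limma) with a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run as alternatives.

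The genes named in the text were chosen by a rule fixed at the same time, and some of the genes it took are not reported here. It took Wnt11 and Hoxb7, and the 10 largest changes toward each side among called genes whose groups did not overlap and whose higher group had a mean of at least 5 RPKM. From each list it took up to 4 called members with the largest change, and the 2 members with the highest mean RPKM where fewer than 2 were called. Other genes named were chosen after their values were seen, among them Gfra1, Sox9, Spry1, Axin2, Tcf7, Wnt7b and Clu, and members that went against their list or missed the threshold. Alternatives changed the pseudocount, the filter, the scaling between libraries, the variance model, the replicate block, the fold threshold and the summing of rows, or left out each library. One more, which left out tip replicate 2 and stalk replicate 1 together, was added after seeing the data. No pair of libraries held the same values, with 55.3% to 72.2% of genes differing by more than 10% within a group, so all 6 were used as separate samples.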

Results

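Gene expression was measured by mRNA sequencing in the tip and stalk compartments of the ureteric epithelium, the branching tree of the embryonic mouse kidney that becomes the collecting ducts. Cells carrying both the Wnt11 and the Hoxb7 reporter (tip) and cells carrying the Hoxb7 reporter without the Wnt11 reporter (stalk) were profiled, with 3 libraries per group. Values are RPKM as deposited by the authors, and levels below are means ± SD over n = 3 libraries. Between 12194 and 12472 genes per library reached 1 RPKM. The sequencing depth behind the values was unknown. The 1 comparison of the design asked how tip and stalk cells of the same epithelium differ.

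Tip cells expressed the growth receptor, transcription factor and feedback genes of the branching ureteric tip, together with genes of DNA replication and mitosis. Stalk cells expressed genes of collecting duct principal cells, intercalated cells and urothelium. Endothelial markers (11 of 11 tested), immediate early and heat shock genes (10 of 16) and genes of the mitochondrial genome (15 of 15) were higher in stalk as well. No list was called by camera once the correlation between genes was estimated. Wnt11 stood at 693 ± 255 RPKM in tip and 11.7 ± 11.6 RPKM in stalk, a 59.2-fold ratio. With 1 library left out, this ratio ranged from 41.8-fold (without stalk replicate 1) to 131-fold (without stalk replicate 3). The water channel gene Aqp2 stood at 575 ± 177 RPKM in stalk and 4.06 ± 1.47 RPKM in tip, a 142-fold ratio. All 16 tested genes of the tip list were higher in tip, and 15 of 16 genes of the stalk list were higher in stalk.

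Of 12532 genes tested with limma, 6089 (48.6%) differed at the Benjamini-Hochberg threshold, 3274 higher in tip and 2815 higher in stalk. Most of the changes were small, with a median absolute log2 fold change of 0.76 among called genes. A change of at least 1 log2 unit was found for 1033 genes higher in tip and 1112 higher in stalk. A change of at least 3 log2 units was found for 30 genes higher in tip and 112 higher in stalk. In 7245 genes (57.8%) the libraries of one group all lay above those of the other, where chance gives 10%. With each library scaled by its median ratio to the others, the split was 2984 genes higher in tip and 3164 higher in stalk. Across genes, log2 values correlated at 0.968 to 0.988 within groups and at 0.818 to 0.875 between groups. The leading principal component, with 82.9% of the variance, separated tip from stalk. On the next component (9.21%), tip replicate 2 (-20.5) and stalk replicate 1 (-25.0) stood apart from the other libraries (7.72 to 18.5). Without these libraries 6020 genes were called, 3103 higher in tip and 2917 higher in stalk, in an alternative chosen after seeing the data.

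**Figure D1:**
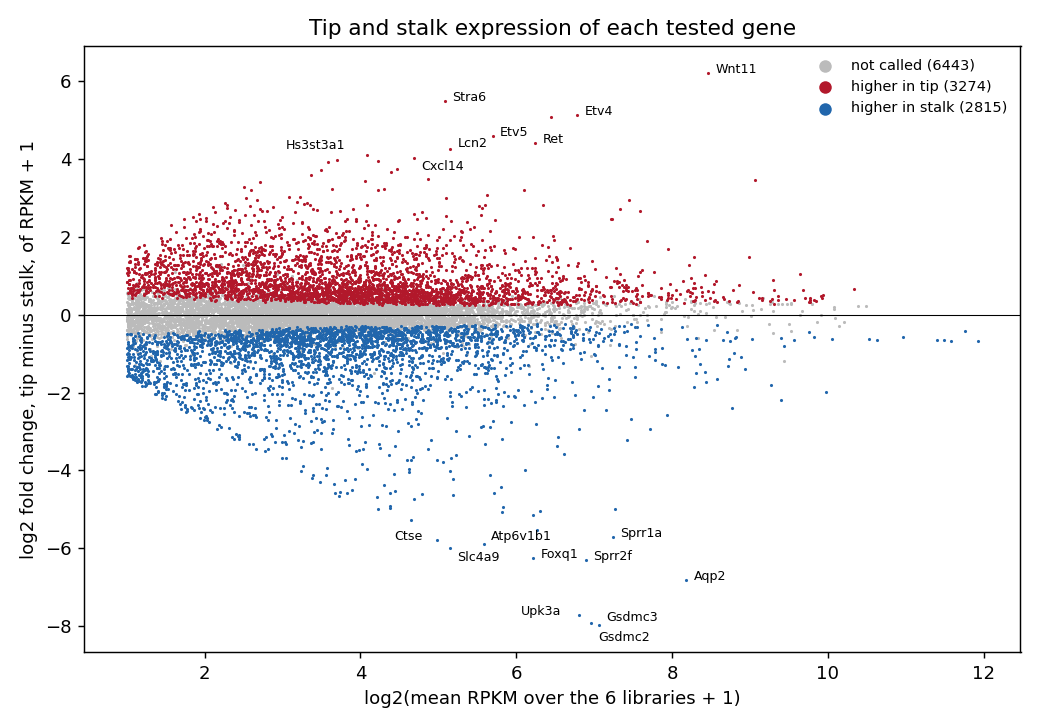
Log2 fold change of RPKM + 1 (tip minus stalk, vertical axis) against log2 of the mean RPKM plus 1 over the 6 libraries (horizontal axis) for each of 12532 tested genes. Points are coloured by the limma call (3274 higher in tip, 2815 higher in stalk), and the labelled genes, from Wnt11 (6.20) to Gsdmc3 (-7.96), are among the 10 largest changes on each side chosen by the fixed rule.

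The reporter genes were examined first, since they defined the sort. Wnt11 (chromosome 7, 98835112 to 98855195, plus strand, mm10) was higher in tip by a log2 fold change of 6.20 (SE 0.68, limma adjusted p = 0.000162). Its level in the stalk libraries ranged from 1.92 RPKM in replicate 1 to 24.5 RPKM in replicate 3. Hoxb7 (chromosome 11, 96286623 to 96290162, plus strand), whose reporter was present in both groups, was at 75.8 ± 22 RPKM in tip and 53.7 ± 14.0 RPKM in stalk. Its difference of 0.48 (SE 0.25) did not pass the test (limma adjusted p = 0.150), but passed without tip replicate 2, with a log2 fold change of 0.73 and an adjusted p of 0.0263 (range over its alternatives 0.0117 to 0.399). Of the reporter list, 1 gene was therefore higher in tip and 1 was not called.

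After Wnt11, the largest change toward tip was that of Stra6, which encodes a membrane receptor for retinol uptake (chromosome 9, 58063788 to 58153996, plus strand). It was at 65.1 ± 16.3 RPKM in tip and 0.481 ± 0.370 RPKM in stalk, with a log2 fold change of 5.49 (SE 0.23, limma adjusted p = 3.94e-06). The ETS transcription factor genes Etv4 (5.14) and Etv5 (4.59) and the GDNF receptor Ret (4.42) were also among the 10 largest. Ret (chromosome 6, 118151745 to 118197718, minus strand) stood at 143 ± 32.1 RPKM in tip and 6.64 ± 4.94 RPKM in stalk. So were the lipocalin gene Lcn2 (4.26), the heparan sulfate sulfotransferase gene Hs3st3a1 (4.11) and the chemokine gene Cxcl14 (4.04). Hs3st3a1 has a close paralog, and its value is uncertain to that extent.

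Transcripts of several of these genes differed between the stalk libraries, with Ret at its lowest in replicate 1 and its highest in replicate 3. The tip list, which holds textbook genes of the ureteric tip, had a median log2 fold change of 2.84. Its members besides those above included the GDNF co-receptor Gfra1 (2.46), Sox9 (1.91) and the sprouty gene Spry1 (1.05). The list differed from other genes by camera (adjusted p = 1.19e-09), but not when the correlation between genes was estimated (adjusted p = 0.233 with an estimated correlation). Feedback and target genes of receptor tyrosine kinase and ERK signalling, of which 6 also stood in other lists, had 12 of 15 tested members higher in tip and 0 higher in stalk. Examples are Spry4 at 11.1 ± 1.57 against 0.930 ± 0.494 RPKM and Ccnd1, which encodes cyclin D1, at 79.3 ± 12.6 against 11 ± 4.42 RPKM. The median was 1.66 and the camera adjusted p was 1.05e-05 (adjusted p = 0.142 with an estimated correlation). The other 3 members did not pass the test: Fosl1 (-1.50, adjusted p = 0.0839), Phlda1 (-0.36, adjusted p = 0.475) and Egr1 (-0.24, adjusted p = 0.546). Without tip replicate 2, 2 members of this list were higher in stalk.

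Among the 15 Wnt pathway targets of the list, 9 were tested and 8 of these were higher in tip, with a median log2 fold change of 2.72. They included the secreted Wnt inhibitor Wif1 (2.86), the R-spondin receptor Lgr5 (2.80), the feedback inhibitors Nkd1 (2.73) and Axin2 (2.64), and Tcf7 (2.72). Lgr5 stood at 9.42 ± 0.635 RPKM in tip and 0.522 ± 0.321 RPKM in stalk. Rnf43 had a log2 fold change of 0.20 and was not called (adjusted p = 0.348). The list was called toward tip by camera (adjusted p = 2.20e-05), a call lost when the correlation was estimated (adjusted p = 0.243 with an estimated correlation). With a minimum mean of 5 RPKM, fewer of its genes were tested and 5 were higher in tip.

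Every tested gene of the cell division lists was higher in tip. All 22 DNA replication genes had positive log2 fold changes, with a median of 1.71. The replicative helicase subunit gene Mcm5 stood at 58.2 ± 6.0 RPKM in tip and 13.6 ± 1.76 RPKM in stalk, and the G1/S cyclin gene Ccne1 at 21.3 ± 1.15 and 4.59 ± 0.0908 RPKM. Mcm3 (2.01) and the chromatin assembly gene Chaf1b (2.02) changed by similar amounts. All 20 mitosis genes were also higher in tip, with a median of 1.67. The topoisomerase gene Top2a stood at 81.9 ± 11.4 RPKM in tip and 17.4 ± 2.14 RPKM in stalk. The mitotic kinase gene Cdk1 stood at 104 ± 8.25 and 25 ± 2.52 RPKM, with Bub1 (2.14) and Ube2c (2.01) close to these. Camera gave adjusted p-values of 4.11e-12 for DNA replication (adjusted p = 0.233 with an estimated correlation) and 9.23e-11 for mitosis (adjusted p = 0.241 with an estimated correlation).

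On the stalk side, the largest changes were those of the gasdermin genes Gsdmc3 (-7.96) and Gsdmc2 (-7.91), neighbouring paralogs on chromosome 15 (63857724 to 63878558 and 63824346 to 63845177, minus strand). They stood at 265 ± 106 and 248 ± 74.2 RPKM in stalk. In tip replicates 1 and 3 both were listed at 0. Reads of the pair may be split between them, so the separate values are uncertain. The uroplakin gene Upk3a (chromosome 15, 85017141 to 85022547, plus strand) followed, at 221 ± 61.6 RPKM in stalk and 0.0231 ± 0.0399 RPKM in tip, with a log2 fold change of -7.73 (SE 0.20, limma adjusted p = 4.74e-07). Aqp2 (chromosome 15, 99579055 to 99584547, plus strand) had a log2 fold change of -6.82 (SE 0.28, limma adjusted p = 3.93e-06). The forkhead gene Foxq1 (-6.25), the anion exchanger gene Slc4a9 (-5.99), the proton pump subunit gene Atp6v1b1 (-5.88) and the protease gene Ctse (-5.79) were also among the 10 largest. The small proline-rich genes Sprr2f (-6.29) and Sprr1a (-5.72), members of a family of near-identical genes, completed them. In tip, Sprr1a stood at 28.7 RPKM in replicate 2, and at 0.551 and 2.40 RPKM in replicates 1 and 3.

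Endothelial markers (median -2.01, 11 of 11 tested called) and immediate early and heat shock genes (median -1.14, 10 of 16 called) lay toward stalk with the groups that follow. Neither list was called by camera with an estimated correlation. All 14 tested genes of principal cells, the water- and sodium-transporting cells of the collecting duct, were higher in stalk (median -3.05). The aquaporin gene Aqp3 stood at 152 ± 12.6 RPKM in stalk and 4.08 ± 2.64 RPKM in tip, where replicate 2 was highest at 6.97 RPKM. The sodium channel subunit gene Scnn1a stood at 40.5 ± 2.66 and 0.834 ± 0.413 RPKM, and Fxyd4, a regulator of the sodium pump, had a log2 fold change of -4.68. Genes of intercalated cells, which secrete acid or base, had 11 of 12 tested members higher in stalk over all genes, and 12 adjusted over the list alone (median -4.17). The ammonia channel gene Rhcg (-5.07), the forkhead gene Foxi1 (-4.96) and the proton pump subunit gene Atp6v1c2 (-4.57) changed most after Atp6v1b1. Atp6v1b1 (chromosome 6, 83742990 to 83758855, plus strand) stood at 93.0 ± 22.6 RPKM in stalk and 0.630 ± 0.565 RPKM in tip. Aqp6 missed the threshold over all genes (-1.29, adjusted p = 0.0575). Camera adjusted p-values were 4.11e-11 for principal cells (adjusted p = 0.233 with an estimated correlation) and 2.75e-09 for intercalated cells (adjusted p = 0.241 with an estimated correlation).

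Genes of urothelium, the lining of the ureter and renal pelvis, had 12 of 13 tested members higher in stalk, with a median of -4.21. Besides Upk3a they included Upk1b at 35.5 ± 17.1 RPKM in stalk and 0.0621 ± 0.0558 RPKM in tip, Fxyd3 (-4.74) and Psca (-4.51). The basal cell factor Trp63 had a log2 fold change of 0.27 and was not called (adjusted p = 0.481). The list had a camera adjusted p of 1.10e-08 (adjusted p = 0.233 with an estimated correlation). The stalk list, of which 11 members also stood in other lists, had a median of -3.40 and a camera adjusted p of 1.19e-09 (adjusted p = 0.233 with an estimated correlation). Besides the genes above, Wnt7b (-4.01) and Clu (-2.94) were higher in stalk. The exception was Cdkn1c, which encodes a cyclin-dependent kinase inhibitor and was higher in tip, at 32.4 ± 4.65 against 14.5 ± 1.41 RPKM (log2 fold change 1.10, adjusted p = 0.000231).

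**Figure D2:**
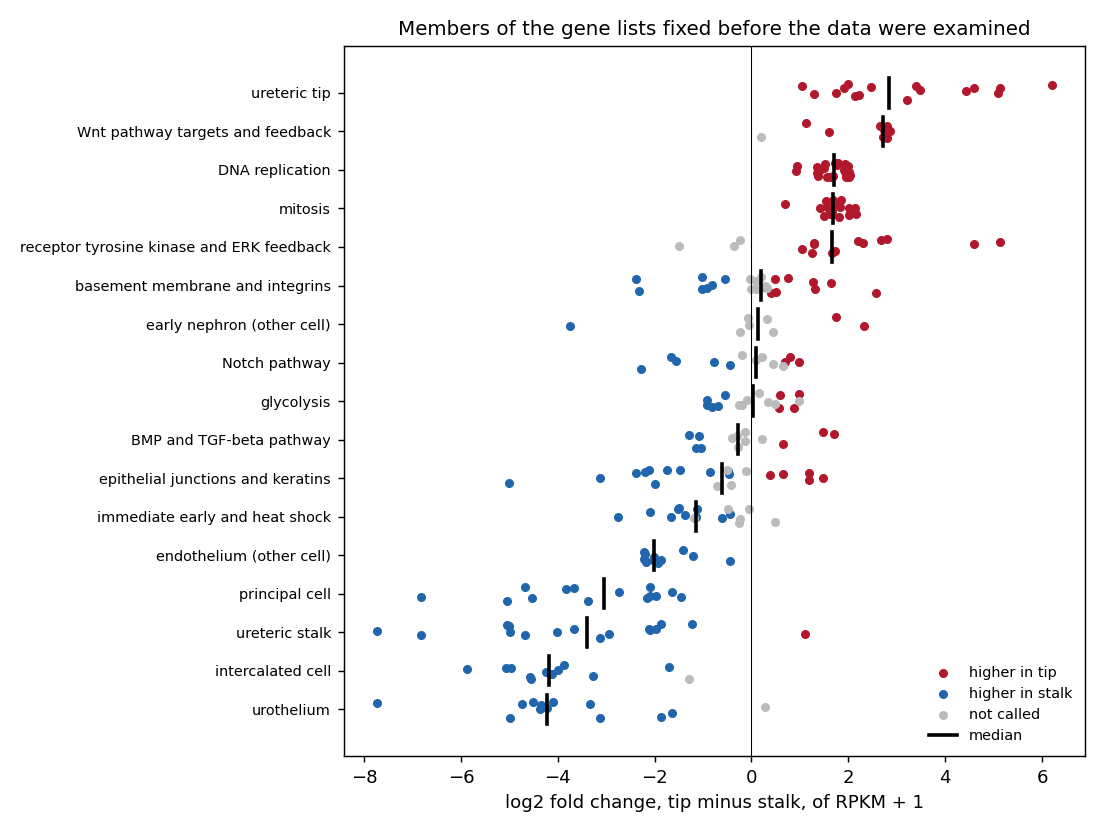
Log2 fold change of RPKM + 1 (tip minus stalk, horizontal axis) of each tested member (point) of the 17 lists with at least 5 tested genes, ordered by their median (black bar). Medians of the tip, Wnt, replication, mitosis and ERK feedback lists lie to the right (1.66 to 2.84). Medians of the collecting duct and urothelial lists lie to the left (down to -4.21). Fosl1, Phlda1 and Egr1 of the ERK feedback list and Trp63 of the urothelium list lie on the other side.

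Epithelial junction and keratin genes went both ways. Of 20 tested, 11 were higher in stalk (13 adjusted over the list alone) and 5 higher in tip. The keratin genes Krt19 (-5.00), Krt7 (-3.13), Krt8 (-2.38) and Krt18 (-2.19) were higher in stalk. Within tip, each was highest in replicate 2, with Krt8 at 260 and Krt18 at 414 RPKM. Within stalk, Krt8 (935 RPKM) and Krt18 (1352 RPKM) were highest in replicate 1, and Krt19 and Krt7 in replicate 2. Krt19 stood at 297 ± 17.6 RPKM in stalk and 9.12 ± 5.02 RPKM in tip. Prom1 (1.47) and Cldn9 (1.20) were among those higher in tip. The median was -0.61 and camera gave an adjusted p of 0.00967 (adjusted p = 0.417 with an estimated correlation). Basement membrane and integrin genes, 23 tested, had 9 higher in tip (10 adjusted over the list alone) and 7 higher in stalk. Frem2 stood at 79.1 ± 15.9 RPKM in tip and 12.5 ± 2.25 RPKM in stalk, and the laminin gene Lama1 (1.65) was also higher in tip, while the laminin gene Lamb3 (-2.38) and the integrin gene Itgb6 (-2.32) were higher in stalk. This list was not called (median 0.20, camera adjusted p = 0.610).

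Notch pathway genes also went both ways, with 3 of 13 higher in tip and 5 higher in stalk. The ligand genes Dll4 (-2.29) and Dll1 (-1.66) and the target gene Heyl (-1.56) were higher in stalk, whereas the target gene Hes1 was higher in tip at 154 ± 6.35 against 78.5 ± 18.0 RPKM (0.99). The list was not called by camera (adjusted p = 0.583). Its median was 0.09 and its mean -0.23, and fry, which does not compare it with other genes, gave an adjusted p of 0.00345 toward stalk. Without stalk replicate 1, 5 Notch genes were higher in tip. Of 13 BMP and TGF-beta pathway genes, 3 were higher in tip and 4 higher in stalk (median -0.27, camera adjusted p = 0.583). Bmp7 stood at 94.3 ± 11.7 RPKM in tip and 28.3 ± 4.89 RPKM in stalk, and Ltbp1, which encodes a binding protein of latent TGF-beta, changed by 1.48. Tgfb2 (-1.28) and Bmp2 (-1.16) were higher in stalk. Without tip replicate 2, 7 genes of this list were higher in stalk. Of 16 glycolysis genes, 4 were higher in tip and 5 higher in stalk (median 0.03, camera adjusted p = 0.870). The hexokinase gene Hk2 (0.88) was higher in tip, and Pfkm (-0.93) and Aldoa (-0.91) were higher in stalk. Gapdh (0.98) was also called, at 12.4 ± 1.39 against 5.84 ± 0.853 RPKM, but its reads may be split with pseudogenes and its value is uncertain. Without stalk replicate 2, 7 glycolysis genes were higher in tip and 3 higher in stalk, and 3 were higher in stalk without tip replicate 1 or without stalk replicate 1.

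Markers of other cell types were examined beside these groups. Many of them had no values or a mean under 1 RPKM and were not tested. Those tested were 11 of 12 endothelial, 4 of 12 stromal, 3 of 12 immune and 2 of 12 erythroid genes. All 11 tested endothelial genes were higher in stalk, with a median of -2.01 and a camera adjusted p of 6.58e-07 (adjusted p = 0.241 with an estimated correlation). Pecam1 stood at 7.39 ± 1.14 RPKM in stalk and 0.857 ± 0.173 RPKM in tip, Cdh5 at 7.54 ± 2.08 and 0.804 ± 0.230 RPKM, and Plvap at 18.9 ± 5.25 and 3.23 ± 0.533 RPKM, with Emcn changed by -2.20. With a minimum mean of 5 RPKM, fewer of these genes were tested and 3 were higher in stalk. None of 4 tested stromal genes was called by limma, nor did any have an unadjusted p under 0.05, with Acta2 at -0.15 (adjusted p = 0.697) and Col3a1 at -0.05 (adjusted p = 0.873). Immune markers were split, with Laptm5 higher in stalk (-2.39), Cd68 higher in tip (0.69) and Ptprc not called (-0.38, adjusted p = 0.143). The erythroid genes Hba-a1 (-0.14, adjusted p = 0.901) and Hba-a2 (0.28, adjusted p = 0.813), a near-identical pair, were not called, and 0 had an unadjusted p under 0.05. Without stalk replicate 1, 2 immune genes were higher in stalk, and without tip replicate 1, 2 or 3, 1 gene of the erythroid list was. The erythroid list also holds Slc4a1, which stood in the intercalated cell list too and was not tested with all 6 libraries. A call in this list need not come from blood cells.

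Among nephron lineage markers, the early nephron list had 2 of 8 genes higher in tip and 1 higher in stalk (median 0.14, camera adjusted p = 0.583). Wnt4, known as an inducer of nephron epithelium, stood at 45.5 ± 2.10 RPKM in stalk and 2.54 ± 0.896 RPKM in tip. Sfrp2 (2.33) and Cxcr4 (1.75), the latter also in the tip list, were higher in tip. Only 3 of the 12 nephron progenitor genes, 4 of 10 podocyte, 3 of 10 proximal tubule and 4 of 10 loop and distal tubule genes were tested. Of the nephron progenitor genes, Cited1 (0.82) and Crym (1.04) were higher in tip, at 2.15 ± 0.253 and 2.23 ± 1.01 RPKM, and Spock2 (-0.52) was higher in stalk. The call of Spock2 was lost without tip replicate 1 (adjusted p = 0.0659), tip replicate 2 (adjusted p = 0.0515) or stalk replicate 2 (adjusted p = 0.0534), and over its alternatives the adjusted p ranged from 0.0110 to 0.0777. Without tip replicate 2, 1 progenitor gene was higher in tip. None of the 4 podocyte genes was called by limma, 1 having an unadjusted p under 0.05, with Podxl at -0.73 (adjusted p = 0.0810) and Synpo at 0.55 (adjusted p = 0.134). Podxl passed without tip replicate 3, at -1.10 with an adjusted p of 0.00480 (range over its alternatives 0.00480 to 0.273). None of the 3 proximal tubule genes was called, 0 having an unadjusted p under 0.05, with Slc34a1 at -0.15 (adjusted p = 0.820) and Spp2 at -1.06 (adjusted p = 0.206). Slc34a1 passed without stalk replicate 1, at -0.76 with an adjusted p of 0.0434 (range over its alternatives 0.0434 to 0.949). Of 4 loop and distal tubule genes, Calb1, which encodes a calcium-binding protein also known from ureteric epithelium, was higher in tip at 327 ± 7.68 against 54.9 ± 26.0 RPKM. Sostdc1 was higher in tip as well (0.71, adjusted p = 0.0253). Its call was lost without tip replicate 2 (adjusted p = 0.0608), tip replicate 3 (adjusted p = 0.0917) or stalk replicate 1 (adjusted p = 0.0643), and over its alternatives the adjusted p ranged from 0.00919 to 0.108. Without tip replicate 3, 1 gene of this list was higher in stalk.

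Immediate early and heat shock genes, which respond to tissue dissociation, were higher in stalk in 10 of 16 cases over all genes. Adjusted over the list alone, 11 were higher in stalk and 1 higher in tip. Without stalk replicate 2, 1 was higher in tip over all genes. The heat shock genes Hspa1b (-2.75) and Hspa1a (-2.09), a near-identical pair, changed most, with Hspa1b at 103 ± 12.6 RPKM in stalk. In tip, Hspa1b stood at 33.5 RPKM in replicate 2, and at 8.88 and 9.65 RPKM in replicates 1 and 3, and Hspa1a was highest in replicate 2 as well. Fosb (-1.66) and the co-chaperone gene Dnajb1 (-1.52) followed, and Fosb stood at 580 ± 218 RPKM in stalk and 181 ± 67.2 RPKM in tip. The median was -1.14 and camera gave an adjusted p of 4.31e-04 (adjusted p = 0.294 with an estimated correlation). Transcripts of the mitochondrial genome made up 7.27 ± 0.440% of the RPKM in stalk and 4.64 ± 0.325% in tip. Those of ribosomal protein genes made up 2.11 ± 0.166% in stalk and 2.74 ± 0.0804% in tip. Both differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. All 15 mitochondrial genes tested were higher in stalk by limma, with a median log2 fold change of -0.66. With no filter on low values 9 of them passed, and with quantile normalization 10.

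**Figure D3:**
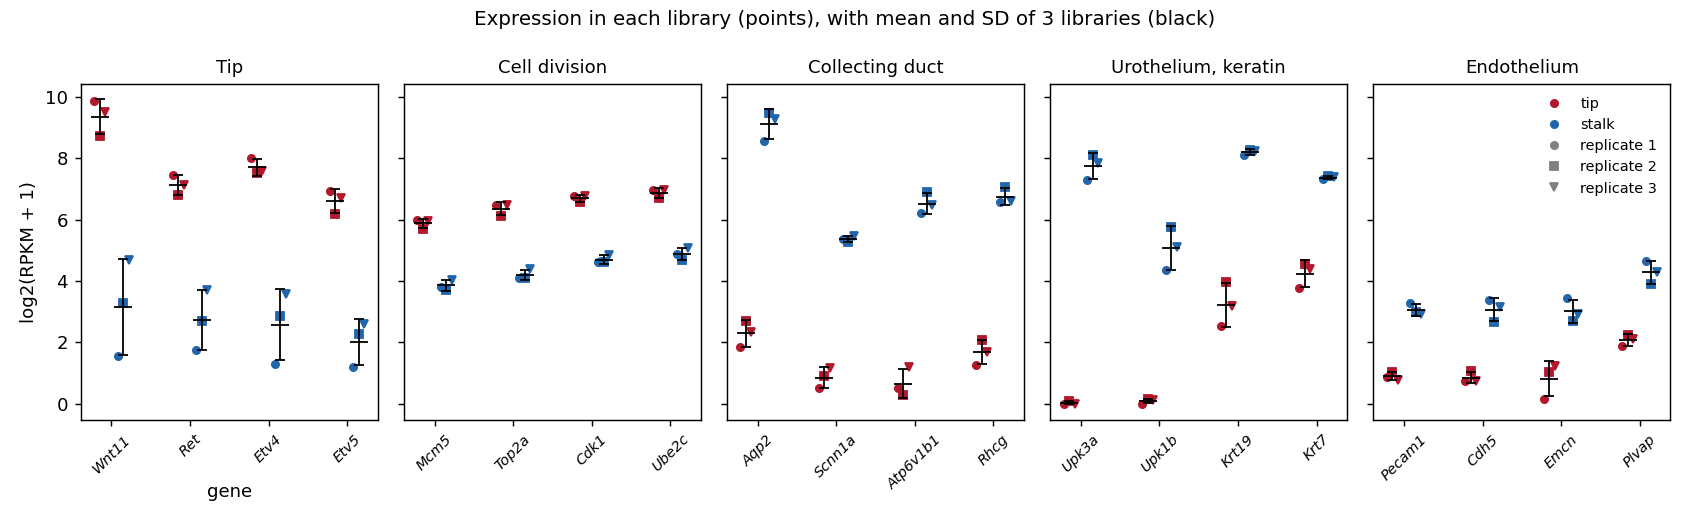
Expression as log2(RPKM + 1) (vertical axis) of 4 genes from each of 5 groups, with 1 point per library shaped by replicate, and the mean and SD of the 3 tip (red) and 3 stalk (blue) libraries in black. Tip and stalk points do not overlap for any gene shown, and the stalk points of Wnt11, Ret, Etv4 and Etv5 are lowest in replicate 1 and highest in replicate 3.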

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

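Every setting tried called genes in both directions, while the counts and the calls of single genes moved. With rows left unsummed, 4506 of the 6089 main calls were kept in the row with the highest mean, 4505 of them in the same direction. Without 1 library, between 4695 (tip replicate 1 left out) and 5383 (stalk replicate 1 left out) of the main calls were kept. Over the pseudocounts, filters, scalings, variance models and summing of rows, between 4642 and 6238 genes were called against 6089. Leaving out 1 library at a time gave 4767 to 5853 genes, 2511 to 3077 higher in tip and 2256 to 2861 higher in stalk. With a change of at least 1 log2 unit required, 2145 genes were called, 1033 higher in tip and 1112 higher in stalk, since most called changes were smaller. Camera called 12 lists under each of the settings that changed the values, libraries or model, except the minimum of 5 RPKM (11), and fry called 13. Camera with an estimated correlation called 0, with 2 lists at an unadjusted p under 0.05, and the cause was not tested. With the replicate number as a block (replicate block), 5096 genes were called, 2716 higher in tip and 2380 higher in stalk, 5061 of them among the 6089, the call of Spock2 was lost (adjusted p = 0.0556) and that of Podxl gained (adjusted p = 0.0419). The deviations of same-numbered libraries correlated at -0.30, -0.34 and 0.09, so the numbers were not taken to pair the samples. Those of tip replicate 2 with stalk replicate 1 correlated at 0.56, tip replicate 3 with stalk replicate 2 at 0.40, and tip replicate 1 with stalk replicate 3 at 0.33. Other differently numbered pairs across groups lay between -0.44 and 0.05. A pairing of the samples under other numbers was not tested. Leaving out tip replicate 2 and stalk replicate 1 together, chosen after seeing the data, gave 6020 genes and 12 lists. Of 1490 values of 89 named genes under the alternatives, 1473 kept their side of the threshold, 12 lost the call and 5 gained it. Among values called in the main or the alternative setting, 0 changed direction. A change of direction of a gene called in neither was not counted. The lost calls were those of Sostdc1, Spock2 and Cd68, and the gained ones those of Hoxb7, Podxl and Slc34a1. Sequencing depth was unknown, so its effect on low genes was not examined.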

Other observations

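The tests of tip cells in the stalk libraries, of the stromal genes and of tip replicate 2 were chosen after the results were seen, as was the grouping by symbol described next; the count of splits and the other endothelial list were fixed before their results.

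Grouping genes by the stem of their symbol gave 69 families of at least 15 tested genes. Each was compared with the remaining genes by a one-sided Fisher's exact test on the calls, adjusted over families. That test takes genes as independent, and correlation between genes was not estimated for families, so its p-values may be too small. For the gene lists, no camera call remained once that correlation was estimated. Nucleoporin genes were higher in tip in 15 of 19 cases and higher in stalk in 0 (adjusted p = 0.000154), with Nup210 at 1.41 and Nup107 at 1.20. Centrosomal Cep genes (17 of 31) and Rad genes (11 of 17), many of which act in DNA repair, were enriched toward tip (adjusted p = 0.0214 for both), as were Cdc genes (16 of 31, adjusted p = 0.0293), and histone and kinesin genes (14 of 27 each, adjusted p = 0.0372). Symbols with the stem Rpl, that of large ribosomal subunit genes, were higher in tip in 34 of 82 cases (adjusted p = 0.0293) with a median of 0.35. The stem can also take in their many near-identical pseudogenes, which may share reads, so these cases may count the same signal repeatedly. The directions of these families held with quantile normalization and with median ratio scaling, although 1 Rpl symbol was higher in stalk under the latter.

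Toward stalk, genes with the stem Atp were enriched, 40 of 61 (adjusted p = 4.61e-11). Among these, 20 of 23 genes of the vacuolar proton pump and its accessory subunits (Atp6) were higher in stalk and 0 higher in tip, with a median of -1.19. They included the broadly used subunit gene Atp6v1a (-1.93), besides the subunits of the intercalated cell list. Of 16 Atp5 genes of the mitochondrial ATP synthase, 10 were higher in stalk, with a smaller median of -0.44. Nuclear genes with the stem Cox, not all of which need encode subunits of the respiratory chain, were higher in stalk in 12 of 23 cases (adjusted p = 0.0404). The respiratory chain gene Cox8a was at -0.88. Solute carrier genes were higher in stalk in 75 of 202 cases (adjusted p = 4.88e-05) and higher in tip in 32. The iron exporter gene Slc40a1 (-3.12) was an example of the former and the fatty acid transport gene Slc27a6 (3.95) of the latter. No direction turned with quantile normalization or median ratio scaling. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 6089 genes by limma, and the highest of the others gave 0 (up to 449 at an unadjusted p under 0.05, against 6919). With 10 splits, a share under 0.05 cannot be reached. Each other split mixed tip and stalk libraries, so their difference widened the spread within its groups. Few calls were therefore fixed in advance there, and no conclusion on chance was drawn.

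Tip transcripts were present in the stalk libraries, and 13 of the 16 tip list genes were higher in stalk replicate 3 than in replicate 1, while Sox9, Spry1 and Cxcr4 ran the other way. Wnt11 stood at 0.276%, 1.25% and 3.54% of its tip level in stalk replicates 1, 2 and 3, but 10 of the other 15 tip list genes lay above 2 times that ratio in all 3, which argues against tip cells at the share that Wnt11 allows as the whole source. Tip cells low in Wnt11 stay open, since the gate removed cells with the Wnt11 reporter. Of 79 abundant tip genes, 97.5% were higher in replicate 3, which restates the difference between replicates. An equal increment for most genes was asked of a larger share of tip cells there. Of the increments, 75.9% lay within a factor of 2 of their median, where 75% was asked. The 95% binomial interval of that share (65.0 to 84.9) held the bound. It takes the genes as independent, though they come from the same libraries, so it may be too narrow. Such a share and a difference in the stalk cells themselves cannot be told apart.

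Endothelial genes were higher in stalk although the gate on the Hoxb7 reporter would remove endothelial cells. In another endothelial list of 20 genes fixed before its test, 10 were tested and 70% of these were higher in stalk. This share lay between the bounds set for and against endothelial cells, and Eng and Ramp2 were higher in tip. Members such as Gpr116 (0.0970 to 0.235 RPKM in tip) passed the filter on mean RPKM only through stalk, so the filter may raise the share. Endothelial cells and expression by stalk cells cannot be told apart. A lower ureteric share that raises every other cell type alike is argued against only for the 4 of 12 stromal genes tested. They had a median log2 change of 0.0846 (SD 0.21), against -2.01 (SD 0.56) for the endothelial genes. The 9 endothelial genes that stood no higher in tip than the highest stromal gene changed by -2.22 to -1.21. Genes low in tip pass the filter on mean RPKM more readily when stalk is high. This range therefore cannot show whether low levels hid a stromal change. The order stalk replicate 1 above 3 above 2 was seen in 10 of the 11 genes of the fixed list but in 4 of 10 of the other, against 14.0% of all genes. No member of the fixed list stood in another list.

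Tip replicate 2 and stalk replicate 1 stood together on the second principal component, and 133 genes were at least 1 log2 unit higher in tip replicate 2 than in both other tip libraries. Stalk cells in tip replicate 2 are argued against, since 96.2% of these genes exceeded the largest share of stalk cells that any principal or intercalated cell gene allowed (13.8%, from Hsd11b2, and 0.384% from Aqp2). Of the 133 genes, 92.5% were also highest in stalk replicate 1, which restates that these libraries deviated together across genes (correlation 0.56), so that a shared state or handling and a chance likeness cannot be told apart. Among the 133 genes were Hspa1b, Hspa1a, Krt8, Sprr1a, Sprr2f, Fosl1 and Phlda1 from the comparisons above and, chosen after its values were seen, the stress response gene Chac1 (18.7 RPKM in tip replicate 2, 0.827 and 0.905 RPKM in the others). A biological difference between the kidneys used was not tested.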
